A study of Mus musculus with 12 samples.

How the data were processed

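The series holds 12 libraries of the bacterial 16S ribosomal RNA gene from C57BL/6 mice aged 49 days, 6 labelled normoxia and 6 labelled hypoxia. The 16S gene is carried by all bacteria, and the variable regions V3 and V4 that were amplified differ between taxa, so reads of this amplicon describe which bacteria are present and in what proportion. Per the labels' protocols, DNA came from the contents of the ileocecal gut, was amplified with 32 PCR cycles and sequenced as paired reads on an Illumina NovaSeq. The source label calls the material feces, so the 2 labels differ on the sampled site. Groups and replicate numbers were taken from the sample titles. The labels name no cage, litter, batch or animal number, so p-values measure only the spread between these samples, which may be technical.

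The main file deposited by the authors holds whole-number read counts per feature and library, where a feature is a distinct amplicon sequence or sequence cluster. The counts are not normalized, and their totals run from 22704 to 68718 per library. The merging of read pairs, the removal of poor reads, the denoising or clustering tool and any taxonomy reference are not given in the sources used here. The smallest count above 0 in any library is 2, so single reads had been removed from each library before deposit. Features carry hexadecimal IDs, and the files used here pair these IDs with neither a sequence nor a taxon. Genera, families, phyla, the genus Desulfovibrio, the ratio of Firmicutes to Bacteroidetes and preset taxon lists had been planned and were not analysed here. The table has 9632 lines, 2 of them empty, and 4324 of the 9630 listed features have no read in these 12 libraries.

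A second file deposited by the authors gives, per library, the number of raw and valid tags as counts, and the percent of bases at quality Q20 and at Q30 and the percent of G or C bases. Its 6 lines for libraries that match no sample of the series were not used. Raw and valid tags are equal in each of the 12 libraries. The share of valid tags that reached the feature table was computed from both files.

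Features with at least 10 counts in at least 4 of the 12 libraries were tested, which left 554 features holding 73.2% to 93.2% of a library's reads. Hypoxia was compared with normoxia by edgeR 4.0.16 with TMM factors, a quasi-likelihood fit and Benjamini-Hochberg adjustment, two-sided, at a threshold of 0.05. TMM factors ran from 0.831 to 1.65, the highest in the hypoxia 4 library. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Counts were simulated for this comparison from the means, library sizes and dispersions within groups of the 554 tested features. In each of 5 draws 200 features were changed, and 355.2 features passed the filter on average. Of the changed features that were tested, edgeR recovered 4.59% at 4-fold, 36.4% at 16-fold and 100% at 1000-fold, with 4.92% of its calls false, and DESeq2 recovered 19.7%, 71.1% and 99.4%, with 9.22% false. With dispersions taken over all libraries, edgeR recovered 5.88%, 27.0% and 100%, with 3.93% false (320.6 features per draw). The 1000-fold size and the dispersions within groups were added after a first simulation with smaller changes had recovered few.

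Features per library were counted after random thinning to 22704 reads, the smallest total, as the mean of 100 draws. Without 1 library, thinning went to the smallest remaining total, with 20 draws. A thinned library can hold features with 1 read, which the smallest library cannot, since single reads had been removed. The Shannon index used natural logarithms. Community composition was compared by Bray-Curtis distances of feature shares, with the share of variance between groups (PERMANOVA R2) tested over the 462 splits of the libraries into 6 and 6. The spread within groups was tested on distances to the group centroid. Differences between the groups in single values were tested by exact two-sided permutation, with sets of features that the group labels define rebuilt in every split, and 0.00216 is the smallest p these tests can give with all 12 libraries. Relations between library measures were tested on 100000 random permutations. R2 and centroid distances were checked against vegan 2.7.1. Intervals and floors cover counting error only, since PCR reads are not independent molecules. A count of 0 in a library allows a share of up to 0.00437% to 0.0132%, set by 3 counts of the library's total. Single reads removed before deposit are not allowed for in these floors.

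The feature IDs to print were set as those with the largest rise and fall among features past the threshold with a mean share of at least 0.1%. The plan was 5 per direction, reduced to 2 because the IDs have no names. Alternatives planned before the data were examined were DESeq2 1.42.0 with poscounts size factors, library size without TMM, no filter, a filter on at least 6 libraries, the replicate number as a block, limma 3.58.1 on centred log ratios with 0.5 added, a robust fit, exact permutation tests on shares, other distances and leaving out each library. Thinning, leaving out the 2 libraries with the fewest reads of their group, and the sets of features found in every library or in 1 group alone were added after the data were seen. The groups share replicate numbers, which no label describes as pairs. No 2 libraries of a group agreed within sampling noise, with chi-square per degree of freedom of 41.8 or more.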

Results

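Gut bacterial communities of mice kept in hypoxia were compared with those of mice kept in normoxia by sequencing a 16S amplicon, in a study of intestinal injury under low oxygen. There were 6 libraries per group. The libraries held 48970 ± 14274 counted reads in hypoxia and 61757 ± 6913 in normoxia (mean ± SD, n = 6 each). The hypoxia 4 library was the shallowest of all, and the normoxia 6 library, with 48981 reads, the shallowest of its group. In total 5306 features had reads. Of these, 830 were found in both groups, 2381 in hypoxia libraries alone and 2095 in normoxia libraries alone, and 3781 were found in a single library.

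The overall makeup of the community differed between the groups. Bray-Curtis distances, which run from 0 for identical to 1 for disjoint communities, averaged 0.702 ± 0.030 (SD, 36 pairs) between groups, 0.619 ± 0.059 (15 pairs) within normoxia and 0.486 ± 0.033 (15 pairs) within hypoxia. Each of the 12 libraries had its nearest neighbour in its own group. Group membership accounted for 31.1% of the variance (exact permutation p = 0.00216, the smallest possible). That share was 19.0% with Aitchison distance and 15.9% with Jaccard distance on presence at equal depth (exact permutation p = 0.00216 each). On the first principal coordinate, which held 31.5% of the positive eigenvalues, the hypoxia libraries lay between -0.264 and -0.205 and the normoxia libraries between 0.152 and 0.266.

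**Figure D1:**
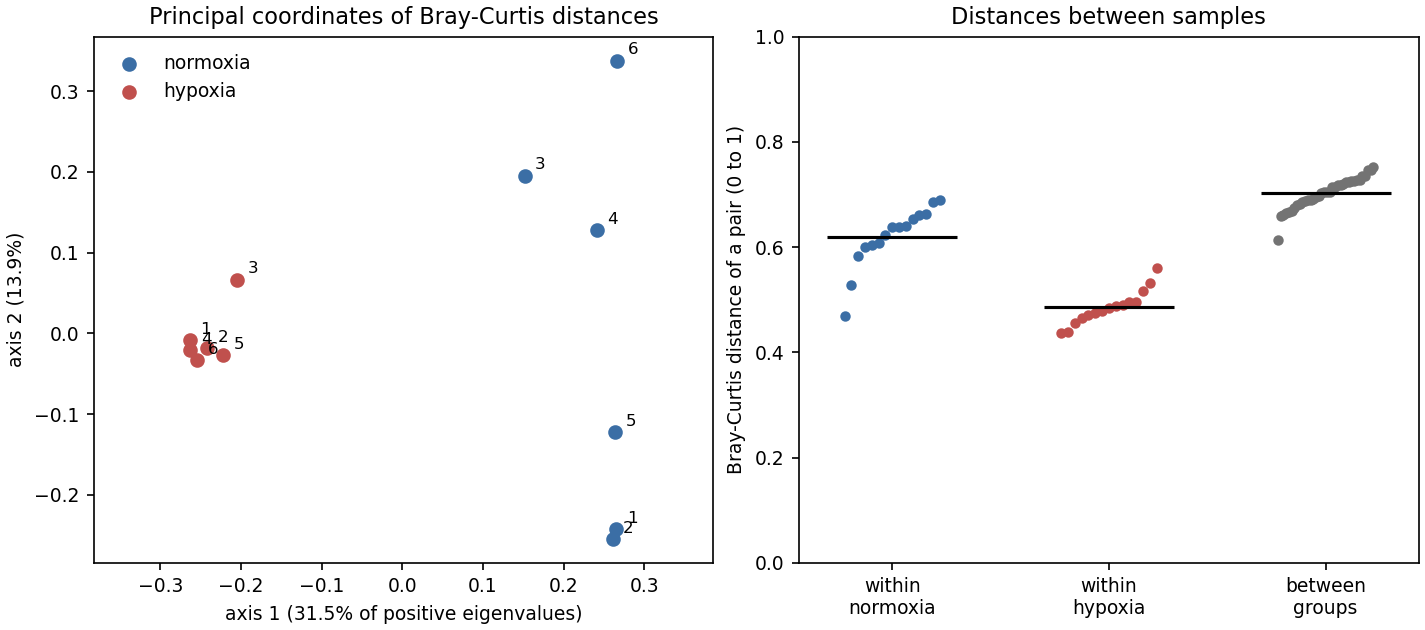
Left, principal coordinates of Bray-Curtis distances between the 12 libraries (numbers are replicates; axes give the percent of positive eigenvalues). Right, each point is the distance of 1 pair of libraries and the bar is the mean; pairs within hypoxia average 0.486, within normoxia 0.619 and between groups 0.702.

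Hypoxia samples resembled each other more than normoxia samples did. The mean distance of a library to its group centroid was 0.313 ± 0.026 in hypoxia and 0.401 ± 0.023 in normoxia (SD, n = 6 each; exact permutation p = 0.00216). The mean distance within hypoxia was lower than within normoxia by 0.133. Spread within groups was examined with Bray-Curtis distance only. The test of composition above also responds to such a difference in spread. The closest pair of normoxia libraries, 1 and 2, lay at 0.469, and the others of that group had their nearest neighbour at 0.529 to 0.604.

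Features found in every library took a larger share of reads in hypoxia. The 64 features present in all 12 libraries held 43.3% ± 5.12 of the reads in hypoxia and 28.3% ± 5.28 in normoxia (SD, n = 6 each; exact permutation p = 0.00216, 0.00866 after Benjamini-Hochberg adjustment over 4 sets of features). Features found in both groups held 79.2% ± 3.36 of reads in hypoxia and 73.6% ± 2.76 in normoxia, a difference short of the threshold when the set was rebuilt for every split of the libraries (exact permutation p = 0.0541, adjusted 0.0866). Features of a single library held 7.99% ± 4.83 in hypoxia and 10.1% ± 1.79 in normoxia, a difference short of the threshold (exact permutation p = 0.353) that passed it without hypoxia 5 (-3.51 percentage points, exact permutation p = 0.0238). These sets were defined from the same libraries after the data were seen. Without the hypoxia 4 and normoxia 6 libraries, the 89 features found in all of the others held 45.8% of the reads in hypoxia and 33.2% in normoxia (exact permutation p = 0.00794, n = 5 each).

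The leading features were partly shared. Of the 10 features with the highest mean share in each group, 3 were common to both, and of the leading 50, 22 were. Among the leading 50 of hypoxia 7 had no read in any normoxia library, and among the leading 50 of normoxia 5 had no read in any hypoxia library. The leading 10 together held 21.2% of hypoxia reads and 18.7% of normoxia reads, and the most abundant feature of a library held 5.40% ± 1.06 in hypoxia and 5.39% ± 1.48 in normoxia.

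Of the 554 features tested, 51 were higher and 56 lower in hypoxia (edgeR quasi-likelihood test, adjusted p under 0.05), and 146 had an unadjusted p under 0.05. The features that rose together held 16.5% ± 4.08 of the reads in hypoxia and 1.30% ± 0.363 in normoxia, and those that fell held 1.08% ± 0.521 in hypoxia and 15.7% ± 4.01 in normoxia. These shares describe features chosen on the same libraries. By mean share over all libraries, 1 rose and 1 fell of the 10 features at 1% or more, 17 rose and 15 fell of the 167 between 0.1% and 1%, and 33 rose and 40 fell of the 377 below 0.1%. The stricter filter of 10 counts in at least 6 libraries left 317 features and 20 calls, all among the 107. Exact permutation tests on shares called 61, of which 30 were among the 107. That test cannot call a feature with reads in only 4 libraries, all of 1 group. In these data its smallest p for 5 libraries, all of 1 group, could not pass adjustment either. Most of the calls with reads in 1 group alone were thus out of its reach, so the overlap of 30 does not show that the others failed. Without the normoxia 4 library there were 65 calls (33 higher, 32 lower), and without normoxia 5 there were 66 (33 and 33). The features that rose numbered 25 without hypoxia 1 or 2, 28 without hypoxia 3, 32 without hypoxia 5 and 26 without hypoxia 6. Those that fell numbered 35 without normoxia 1 and 36 without normoxia 2. Part of these falls came from the filter, which was applied again each time. Without hypoxia 1, 86 of the 107 were still tested and 79 still called. These numbers were 86 and 78 without hypoxia 6, and 89 and 83 without normoxia 1. They were 86 and 65 without normoxia 4, and 85 and 65 without normoxia 5.

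Most called features were present in 1 group alone. Of the 107, 92 had no read in any library of the other group, 43 of them found in hypoxia and 49 in normoxia. These 92 were all of the tested features with reads in 1 group alone. Of the calls, 77 reached 10 counts in only 4 or 5 libraries. In simulated counts the same test recovered 4.59% of 4-fold, 36.4% of 16-fold and 100% of 1000-fold changes among changed features that passed the filter. Changed features that failed the filter are not counted in these percents. Of the 554 features simulated, 355.2 passed the filter per draw on average, so the simulated counts met it less often than the real ones. Changes of 4-fold and 16-fold were thus mostly missed in the simulated counts, and recovery in the real counts may differ. The remaining 15 calls had reads in both groups, and 8 of them were higher and 7 lower in hypoxia. Only 7 of the 64 features found in all 12 libraries passed the test, 5 of them higher and 2 lower, with log2 fold changes from -2.74 to 2.65.

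**Figure D2:**
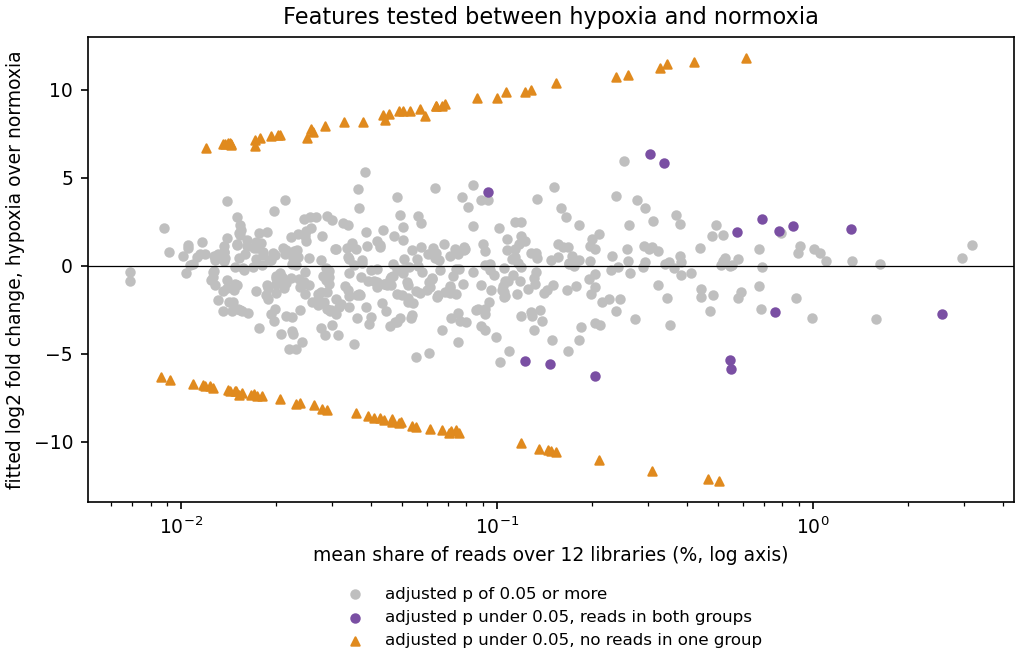
Each point is 1 of the 554 tested features; the horizontal axis is its mean share of reads over 12 libraries in percent on a log scale, and the vertical axis the fitted log2 fold change of hypoxia over normoxia. The 92 called features with no read in one group (triangles) form the outer bands, where the fitted value depends on the fit's prior count, and the 15 other calls lie between them.

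The 2 called features with a mean share of 1% or more, singled out after their values were seen, were found in every library. The feature that led the normoxia group fell from 4.39% ± 2.10 of reads in normoxia to 0.737% ± 0.526 in hypoxia, a log2 fold change of -2.74 ± 0.61 (SE, n = 6 each; edgeR adjusted p = 0.0104). The other rose from 0.412% ± 0.337 in normoxia to 2.22% ± 0.885 in hypoxia, a log2 fold change of 2.10 ± 0.58 (SE; edgeR adjusted p = 0.022).

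The largest differences by the preset rule were in features with no detected read in 1 group. Feature efe72b14727ec47b39fab05af9bd6983 had 158 to 483 counts in each of the 6 hypoxia libraries, a mean share of 0.84% ± 0.47 (SD), and no read in normoxia (edgeR adjusted p = 2.38e-04). Feature 624c71a825d565de8933bec768255ac4 averaged 1.23% ± 1.94 in hypoxia but was found in only 4 of the 6 libraries, with 1093 and 1142 counts in hypoxia 4 and 6, and had no read in normoxia (edgeR adjusted p = 0.0161; 0.163 by the exact permutation test on shares). Feature b02746d92cd34bf02d097cf30611957b had 242 to 938 counts in each of the 6 normoxia libraries, a mean share of 0.929% ± 0.411, and no read in hypoxia (edgeR adjusted p = 1.70e-04). Feature 199c5df50e3db996690096ff3df73d7a was also found in all 6 normoxia libraries, from 16 to 1838 counts with a mean share of 1.01% ± 1.36, and had no read in hypoxia (edgeR adjusted p = 0.00317). The floor was 3 counts over all reads of the group without the feature. Against it, the first feature was 1038-fold and the second 1515-fold higher in hypoxia, and the third 910-fold and the last 991-fold lower. The floor takes no account of single reads removed before deposit, so these values are not strict lower limits. The value of the second was 629-fold without hypoxia 4, and that of the last 627-fold without normoxia 1.

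**Figure D3:**
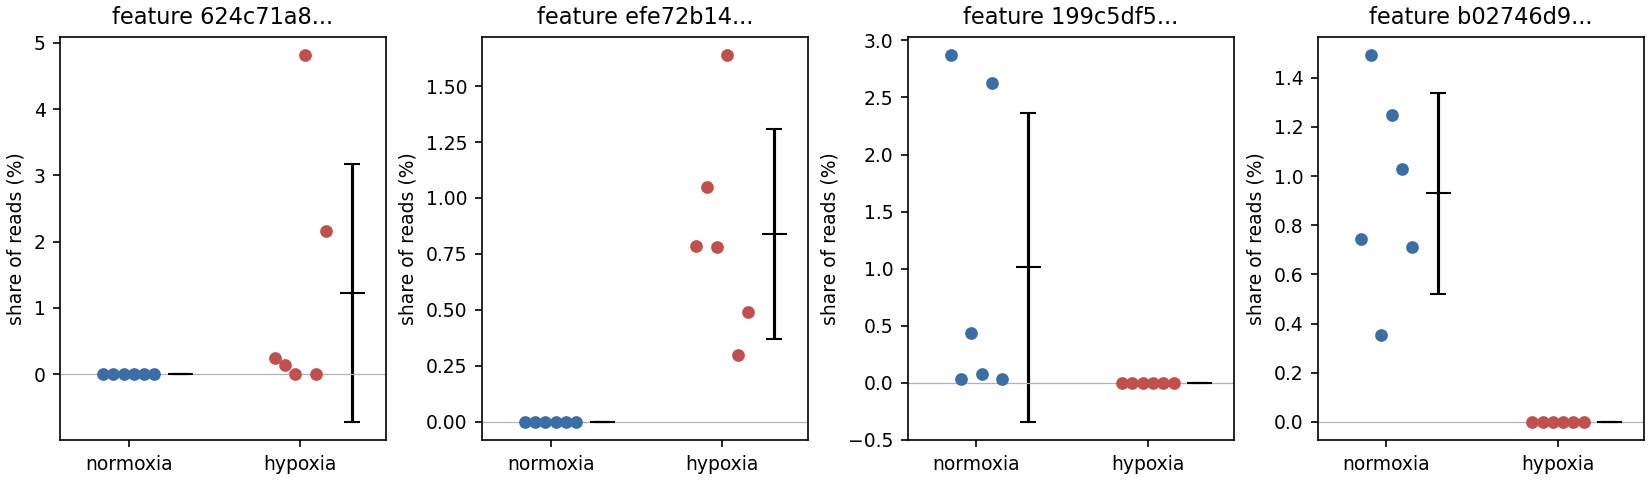
Share of reads in percent of the 4 named features in each library (points), with mean and SD beside them (bars, n = 6 per group); titles give the first 8 characters of the feature ID. The 2 features on the left have no read in normoxia and the 2 on the right none in hypoxia.

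Presence in every library of 1 group and absence from the other was seen for 19 features. Of these, 5 were found in all hypoxia libraries and in no normoxia library, and held 2.52% ± 0.740 of hypoxia reads. The other 14 were found in all normoxia libraries and in no hypoxia library, and held 3.87% ± 1.22 of normoxia reads. Over the 462 splits of the 12 libraries into equal groups, no other split gave more than 2 such features (exact permutation, 1 of 462). Without the hypoxia 4 library, 15 features were exclusive to hypoxia and 14 to normoxia. With 5 libraries in each group, without hypoxia 4 and normoxia 6, the numbers were 15 for hypoxia and 21 for normoxia.

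Diversity within a library did not differ beyond the spread. At the depth of the smallest library, hypoxia libraries held 822 ± 305 features and normoxia libraries 817 ± 157 (SD, n = 6 each; exact permutation p = 0.968). The Shannon index was 5.37 ± 0.33 in hypoxia and 5.52 ± 0.13 in normoxia (exact permutation p = 0.416), and the difference of -0.15 was -0.01 without the hypoxia 4 library. The hypoxia 4 library held 254 features, against 728 to 1102 in the others of its group. Without it, libraries were thinned to 44101 reads, the smallest remaining total. At that depth the mean difference became 133 features higher in hypoxia (exact permutation p = 0.234, n = 5 against 6). The direction was not stable: the difference was -55.7 without normoxia 6, -50.7, -25.6, -29.2 and -6.12 without hypoxia 1, 3, 5 and 6, and -75.0 over features of at least 10 counts.

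**Figure D4:**
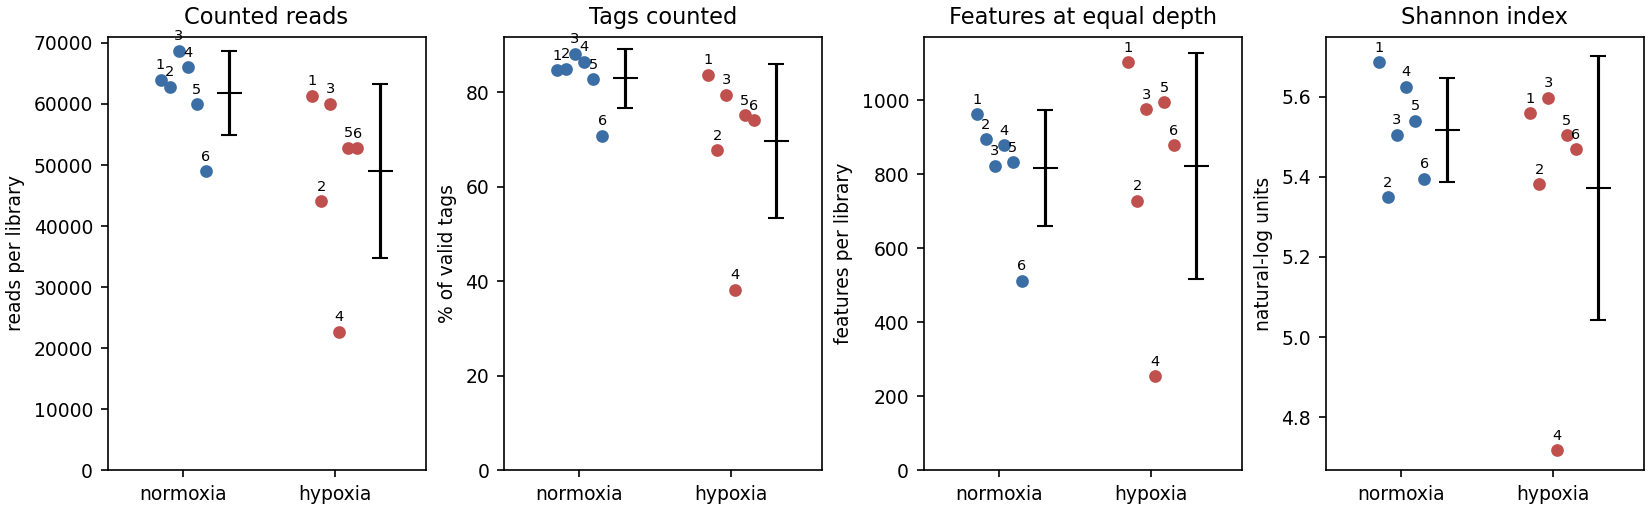
Counted reads, percent of valid tags counted, features after thinning to the smallest total and Shannon index of each library (points numbered by replicate; bars are mean and SD, n = 6 per group). The hypoxia 4 library is the lowest in all 4 panels.

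Libraries also differed in read quality. The share of valid tags that reached the feature table was 69.7% ± 16.3 in hypoxia and 82.9% ± 6.23 in normoxia (SD, n = 6 each; exact permutation p = 0.0476, 0.233 after adjustment over 10 library measures). The percent of bases at Q30 was 89.1 ± 5.43 in hypoxia and 92.5 ± 2.12 in normoxia (exact permutation p = 0.158), and the percent of G or C was 54.3 ± 0.44 and 54.7 ± 0.21 (exact permutation p = 0.0931). Across the 12 libraries, the percent of bases at Q30 and the share of tags counted went together (Pearson r = 0.989, permutation p = 2.00e-05; Spearman rho = 0.944, permutation p = 3.00e-05; adjusted over 3 relations 6.00e-05 and 9.00e-05). Without the hypoxia 4 and normoxia 6 libraries r was 0.958, and within groups it was 0.995 in hypoxia and 0.989 in normoxia. The share of tags counted and the features at equal depth gave r = 0.827 (permutation p = 0.00585, adjusted 0.00585) and rho = 0.434 (permutation p = 0.162, adjusted 0.162). Over both groups together the relation was weaker without hypoxia 2 and 4 (r = 0.412). Within hypoxia r was 0.989. Apart from hypoxia 4, its libraries held 728, 878, 994, 976 and 1102 features at 67.7%, 74.1%, 75.1%, 79.5% and 83.6% of tags counted. Within normoxia r was 0.886, but that value rested on normoxia 6 (70.8% of tags, 512 features). Among the other normoxia libraries, normoxia 3 had the highest share of tags counted (88.2%) and the fewest features at equal depth (823).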

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

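Of the tests in this part, that on rare features was chosen after the result was seen. Among 28 groups of 6 values checked for a library standing apart, 9 were marked, where chance marks about 1 in 20, and the 9 concern only 2 libraries. In hypoxia 4, the share of tags counted was 38.2% (the next library 67.7%), the percent of bases at Q30 was 78.6 (next 88.9), at Q20 90.7 (next 96.1), and the Shannon index was 4.72 (next 5.38). In normoxia 6, the share of tags counted was 70.8% (next 82.7%), the percent of bases at Q30 was 88.2 (next 92.8), at Q20 95.5 (next 97.6), the features found were 519 (next 873), and the features at equal depth were 512 (next 823).

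The few features of hypoxia 4 were set against 2 technical explanations. With the other 5 hypoxia libraries thinned to its total, these kept 728 to 1102 features. Hypoxia 4 held 254, a gap wider than their own range. This argues against fewer counted reads alone, but the gap is inflated. Single reads had been removed before deposit, while thinning leaves features with 1 read that count as found. The size of this effect was not examined, and it may also touch the rare features below. A loss of rarer features together with the reads removed before counting is consistent with the tables: of features common to 4 other hypoxia libraries with a mean share under 0.05%, hypoxia 4 held 15.2%, against 53.2% to 81.5% for each other library at equal depth. Of those from 0.05% to 0.5% it held 58.8%, against 83.0% to 98.3%, and of those at 0.5% or more 97.1%, so the loss was not confined to the rarest features. A community poorer in rare bacteria in that sample would give the same values and stays open, since no second library of it was analysed here.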

How the results depend on the processing

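The alternatives that thin the counts, leave out both hypoxia 4 and normoxia 6 or keep the tested features alone, and all alternatives on features of 1 library, of 1 group or of every library, were chosen after the results were seen. The share of variance between groups and the smaller within-hypoxia distance kept their direction and stayed past the threshold under every alternative run, including the replicate block (31.1% and -0.133, exact permutation p = 0.0312 each, the smallest possible within pairs). The share of variance was smaller with Aitchison (19.0%) and Jaccard distance (15.9%). The within-group distance was examined with Bray-Curtis distance alone. The Shannon difference (-0.15) stayed short of the threshold throughout and ran from -0.19 to -0.01 without 1 library. The count of called features (107) moved with several choices: 20 with 10 counts in at least 6 libraries (30 of the 107 were still tested), 31 with the replicate block (27 shared), 61 with exact permutation tests, and 65 to 103 without 1 library. The other alternatives gave 76 to 155 calls, among them DESeq2 with 141 (7 adjusted p not available) and no filter with 84, of which 48 were among the 107, with an unadjusted p under 0.05 for 3187 of 5306 features. The same-numbered libraries did not deviate together, and of the 6 pairs only number 5 correlated best with its own number, so calls lost under the block are not read as weaker. The median log2 fold change of the tested features was -0.25 with TMM, -0.09 with library size alone, -0.12 with DESeq2 and 0.20 with centred log ratios, and changes are relative to these. Named features kept their direction in every fit that tested them, and 1 of them, found in 4 hypoxia libraries, did not pass the permutation test on shares (adjusted p = 0.163). The difference in features at equal depth (4.97) was never past the threshold and changed sign with features of at least 10 counts alone (-75.0), and ran from -55.7 to 133 without 1 library; the cause was not tested. The difference in reads of single-library features (-2.11 percentage points) ran from -4.07 to -0.974 without 1 library, and passed the threshold only without hypoxia 5 (-3.51, exact permutation p = 0.0238). The number of features exclusive to a group (19) was 36 without both hypoxia 4 and normoxia 6, and 19 to 29 without 1 library. Those found in hypoxia alone numbered 15 without hypoxia 4 and 5 to 8 without any other hypoxia library, so the rise to 29 followed it. The difference in reads of features found in every library (43.3% against 28.3%) ran from 11.2 to 16.7 percentage points without 1 library. Fits on genera, families, phyla, Desulfovibrio, the Firmicutes ratio and taxon lists, and genus-level diversity and distances, were not run. Depth limits the detection of rare features, most of all in hypoxia 4.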

Other observations

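The tests against the detection floor, on thinned counts and on the tested features alone were chosen after the results they concern were seen. The features exclusive to a group were set against technical explanations. The median exclusive feature had a mean share 247 times the floor of 3 counts in the group that lacked it. For that feature this argues against a place near the limit of detection. Presence in every library of a group already favours abundant features, and the median does not speak for the weaker ones. At least 69.4% of each library's reads lay in features that the other group also held. This argues against amplicons trimmed differently between groups, since these would share few IDs. Different denoising could leave most IDs shared, so the value does not decide on it. For the 107 called features, 1 of 100 splits of the 12 libraries, the real one, gave as many, and the highest other split gave 1. This argues against a random division of the libraries as the source of that count. Only 100 of the 462 splits were run, and the libraries were treated as independent. A hypothesis that stays open is that the groups held different strains before the treatment, through housing, litter or supplier: 0 labels name any of these, so it cannot be told apart from an effect of hypoxia.

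Tested features with reads in 1 group alone numbered 92, against a median of 6 and at most 53 over the other splits of the 12 libraries.

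The smaller distance between hypoxia samples was tested against 2 technical explanations. With all libraries thinned to the smallest total the difference was -0.130 (exact permutation p = 0.00216), which argues against depth. Over the 554 tested features alone it was -0.127 (exact permutation p = 0.00216), which argues against rare and single-library features. Shared housing of the hypoxia mice could also lower their distances, and like an effect of hypoxia it stays open and untested.

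Some features may not be independent. Among 317 features with 10 counts in at least 6 libraries, 5 pairs kept a constant ratio across the 12 libraries within counting error (chi-square p above 0.05), against at most 3 pairs in 100 shufflings of each feature within its group. This small excess is consistent with several 16S copies of 1 strain being counted as separate features, and in 2 of the 5 pairs both features were called. Ecological dependence between strains was not tested.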
